A study of Mus musculus with 10 samples.

How the data were processed

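The deposited read counts per gene of 10 libraries were used for every test, and the deposited CPM table (reads scaled to the library total) was used to check them. Per the labels, the libraries are 3′ digital gene expression libraries of polyA RNA, aligned to mm10 with STAR 2.6.0a and counted with HTSeq. The annotation release and the strand setting are not given in the sources used here. Each count file listed 31053 genes, and 5 HTSeq summary lines were taken off before any total was formed; they held 62.7% to 68.4% of all reads. Most of these were reads with several alignments (56.4% to 62.4%). CPM values divided by the smallest positive value of their library lay within 0.01 of a whole number. The rounded values equalled the counts for 310530 of 310530 entries. A count test on the reads recovered in this way called 2289, 348 and 1870 genes, all of them shared with the counts. Gene symbols were attached by Ensembl ID from a reference name table (30934 of 31053 IDs matched), and positions came from GENCODE vM21 on GRCm38/mm10.

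The groups were 2iL without DOX (n = 4), 96 h without DOX (n = 3) and 96 h with DOX (n = 3). Genes were kept with filterByExpr by group (minimum count 10), which left 11215 genes. Libraries were scaled by TMM (factors 0.911 to 1.09). edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with robust dispersion to all 10 libraries, and each comparison was a contrast of group means. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Levels are TMM-scaled CPM as mean ± SD over libraries. Levels and sums of fibroblast, macrophage and liver markers, and of Xist, are CPM without TMM scaling. Log2 fold changes carry a standard error (SE) taken from the size of the fold change and the quasi-likelihood F statistic.

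Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of each comparison by Benjamini-Hochberg. The test was repeated with an estimated correlation and with fry. Results with fry are given only for lists whose call with DOX against no DOX was lost with an estimated correlation. The 22 lists, their member genes, the groups, the comparisons and the threshold were chosen before the data were examined. They covered naive pluripotency, general pluripotency, formative and post-implantation epiblast, neural, primitive streak and mesoderm, endoderm, trophoblast, fibroblast, beta-catenin response, STAT3 response, ERK response, Nodal and Smad response, DNA methylation machinery, germline genes silenced by methylation, 2-cell-like state, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cholesterol synthesis, p53 response, stress and integrated stress response, and proliferation. Lists of basement membrane genes, epithelial junctions and Notch targets were added after the values had been seen. Member counts are given after adjustment over all tested genes and adjusted over the list alone.

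Genes that could be named were picked by a fixed rule, and the text describes only part of them. It took a set of markers chosen in advance, the 6 rising and 6 falling genes with the largest fitted change in each comparison, and up to 2 genes per direction from each list. The largest changes required an adjusted p below 0.05, a mean of at least 10 CPM in the higher group and no overlap of CPM values between the groups; genes with only a numbered or clone name were skipped. Among the others, 1 result is not reported here. Fold changes of genes with 0 reads in a group are given as lower bounds from a floor of 3 counts over that group. Genes with 1 to 3 reads in the lower group are given as ratios of reads with exact 95% counting intervals.

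Gene counts, named genes and the 22 lists were tested again without each library in turn, within experiment 1 alone, with the experiment or the experiment and library number as a replicate block, and with other filters and scalings. Gene counts and named genes were also tested with only the 2 compared groups, limma-voom, limma on log2(CPM + 1) and DESeq2 1.42.0. The share of the 2iL-removal change that was absent with DOX was repeated without each library and with other filters. It was also repeated with RLE scaling and the experiment as a replicate block. The added lists were repeated only without each library and within experiment 1, and the tests of differences between experiments were not repeated. Experiment 2 held 1 library in each 96 h group, so it gave fold changes without a test. Experiment 1 held 2 libraries in each group, and 96 h DOX exp1_2 was 1 of its 2 DOX libraries. The comparison of 96 h with and without DOX was also tested on simulated data. These used 1 mean CPM per gene over all 10 libraries and the fitted dispersions. Genes nearly absent from 1 group were therefore not simulated at their own levels. Data simulated without an effect of DOX gave reference values for the share absent with DOX, a test added after the values had been seen. Principal components used log2 CPM of the 500 most variable genes with a prior count of 2.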

Results

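Gene expression was measured in E14 mouse embryonic stem (ES) cells that carried an integrated Esrrb construct inducible by doxycycline (DOX). Esrrb is a nuclear receptor of the naive pluripotency network. The cells were kept in 2iL, in which the GSK3 inhibitor CHIR99021 (3 µM), the MEK inhibitor PD0325901 (1 µM) and the cytokine LIF hold naive pluripotency (4 libraries). Other cells were collected 96 h after 2iL was removed, without DOX (3 libraries) or with DOX (3 libraries). Reads came from 3′ ends of polyA RNA. The 2iL libraries held 3303329 (exp1_1), 3586901 (exp1_2), 3304011 (exp2_1) and 2769071 (exp2_2) reads in genes. The 96 h libraries without DOX held 3364638 (exp1_1), 4715450 (exp1_2) and 3483278 (exp2_2), and those with DOX held 4161567 (exp1_1), 3010462 (exp2_1) and 1253620 (exp1_2). The median was 3334320 reads, and 12659 to 14723 genes were detected per library. Titles name experiments 1 and 2, but nothing says that the libraries came from separate cultures, so the p-values measure the spread between these samples. Intervals and floors built from read counts cover counting error only.

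The 96 h DOX library exp1_2 stood apart from the other 9 in its makeup. Gm42418, a gene that overlaps ribosomal RNA sequence, took 14.8% of its reads against 3.39% to 6.61% elsewhere. Mitochondrial protein genes took 3.10% (0.559% to 1.27% elsewhere), and ribosomal protein genes took 7.10% (13.1% to 16.4% elsewhere). The collagen genes Col1a2 and Col1a1, which fibroblasts express strongly, reached 1288 and 595 CPM there. This library was also deposited under a later date than all the others, so a batch of its own cannot be told apart from the library itself, and the values without it are the values within the other batch. Correlations across genes ran from 0.934 to 0.961 between 2iL libraries, from 0.923 to 0.947 without DOX, and from 0.866 to 0.939 with DOX. The first principal component held 67.6% of the variance and the second 16.2% (figure on principal components; figure on genes of other cell types).

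Esrrb (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628) fell from 315 ± 62.7 CPM in 2iL to 23.1 ± 9.24 CPM at 96 h without DOX (mean ± SD, n = 4 and 3). The log2 fold change was -3.78 ± 0.33 (SE; edgeR's quasi-likelihood test, adjusted p = 7.58e-08), with -4.04 within experiment 1 and -3.36 within experiment 2. Esrrb did not rise with DOX: the level was 18.2 ± 7.71 CPM, a log2 fold change of -0.32 ± 0.33 against no DOX (adjusted p = 0.704). Single DOX libraries held 12.8 (exp1_1), 27.0 (exp2_1) and 14.7 CPM (exp1_2), against 23.8, 13.6 and 32.0 CPM without DOX. The 95% interval ran from -1.01 to 0.38, and the within-experiment values were -0.42 and -0.24. Reads at the 3′ end of Esrrb check the construct only if the construct carries that 3′ end, which is not given in the sources used here. No cells with DOX in 2iL and no line without the construct were collected, so effects of DOX itself cannot be separated from effects of Esrrb.

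Removal of 2iL showed how ES cells leave naive pluripotency when its signals end. Tfcp2l1 (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168), a transcription factor downstream of LIF and STAT3, fell from 918 ± 60.4 to 30.4 ± 7.22 CPM (log2 fold change -4.92 ± 0.34, n = 4 and 3). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a STAT3 target, fell from 235 ± 25.7 to 13.0 ± 2.42 CPM (-4.18 ± 0.27). Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724), which sustains Nanog expression, fell from 214 ± 25.0 to 13.0 ± 1.88 CPM (-4.04 ± 0.25). Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), a core factor of the naive network, fell from 220.0 ± 24.3 to 18.4 ± 4.17 CPM (-3.59 ± 0.31). Zfp42 (ENSMUSG00000051176, chromosome 8, 43295063 to 43306980), the naive marker Rex1, fell by 3.30 ± 0.29 log2 units, and Klf2, a factor that MEK inhibition sustains, fell by 2.31 ± 0.24 log2 units. Crxos, a homeobox gene of ES cells, fell by 5.86 ± 0.35 log2 units. Within experiments 1 and 2 the log2 fold changes were -5.18 and -4.54 for Tfcp2l1, -4.20 and -4.04 for Klf4, and -3.63 and -3.42 for Nanog. Pou5f1, the pluripotency factor Oct4, stayed at 46.1 ± 10.6 CPM against 42.6 ± 13.3 CPM in 2iL, while Sox2 fell from 338 ± 58.7 to 169 ± 47.3 CPM. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 6.14e-09 for Tfcp2l1, 2.48e-09 for Klf4, 7.47e-08 for Nanog, 0.00429 for Sox2 and 0.870 for Pou5f1. Within experiment 1 the call for Sox2 was lost (-0.85; adjusted p = 0.151).

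Genes of the formative and post-implantation epiblast rose. Dnmt3b (ENSMUSG00000027478, chromosome 2, 153649450 to 153687730), a de novo DNA methyltransferase, rose from 176 ± 14.7 to 1832 ± 205 CPM (log2 fold change 3.38 ± 0.24). Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443), its relative, rose from 30.1 ± 7.11 to 260.2 ± 38.3 CPM (3.11 ± 0.25; 2.86 within experiment 1 and 3.40 within experiment 2). Fgf5 (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030), the classic epiblast marker, rose from 0.399 ± 0.127 to 22.3 ± 7.95 CPM (5.66 ± 0.61). Otx2 (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), which drives exit from the naive state, rose from 30.3 ± 15.1 to 264 ± 39.8 CPM (3.12 ± 0.32; 2.64 and 3.84). Pou3f1 (ENSMUSG00000090125, chromosome 4, 124656807 to 124660655), a factor of epiblast and early neural cells, rose from 8.06 ± 2.09 to 249.6 ± 85.2 CPM (4.95 ± 0.36). The adjusted p of these 5 genes ran from 6.36e-09 (Dnmt3b) to 9.46e-07 (Fgf5). Among neural genes, Sox11 and the imprinted gene Nnat rose by 3.28 ± 0.26 and 3.83 ± 0.33 log2 units. The early neural factors Sox1 (adjusted p = 0.0689 by edgeR's quasi-likelihood test) and Pax6 (0.150) did not pass.

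Targets of several signalling pathways changed as well. Lefty2 (ENSMUSG00000066652, chromosome 1, 180893108 to 180899103), a Nodal antagonist and Smad2 target, fell from 487 ± 126 to 8.93 ± 1.58 CPM (log2 fold change -5.77 ± 0.33). Smad7, an inhibitory Smad, fell from 41.6 ± 8.99 to 2.11 ± 0.669 CPM, and Tdgf1, the Nodal co-receptor, fell from 156 ± 9.05 to 24.4 ± 6.28 CPM. The LIF receptor gene Lifr fell by 2.03 ± 0.35 log2 units, and Bcl3, a STAT3 target, fell from 60.3 ± 3.60 CPM in 2iL by 3.36 ± 0.37 log2 units. Dusp4, an ERK phosphatase, rose from 4.98 ± 2.77 to 67.7 ± 11.8 CPM (4.71 log2 units within experiment 1 and 3.04 within experiment 2), and Dusp6 rose by 1.29 ± 0.25 log2 units. Axin2 and Sp5, targets of beta-catenin, fell by 2.74 ± 0.54 and 4.42 ± 0.73 log2 units (Sp5 -2.84 within experiment 1 and -5.08 within experiment 2). The lactate transporter Slc16a3 rose from 29.4 ± 7.64 to 385 ± 151 CPM, and hexokinase Hk1 fell from 123 ± 14.2 to 21.6 ± 9.40 CPM. The cytokine gene Osm fell 96.2-fold by reads (95% counting interval 26.3 to 799.7), and the meiosis gene Tdrd1 rose 75.1-fold (20.4 to 626). Lef1, a partner of beta-catenin, rose by 2.24 ± 0.53 log2 units, and by 3.06 without 2iL exp2_1, with 4.46 within experiment 1 and 0.82 within experiment 2.

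In total, edgeR called 2289 of 11215 genes after removal of 2iL (1291 up and 998 down), 1140 and 814 of them by at least 2-fold. Within experiment 1 alone 1226 genes were called, 1147 of them shared. The naive list fell (19 of 20 genes, 20 adjusted over the list alone, median log2 fold change -3.28, camera adjusted p = 4.09e-41). The formative list rose (16 of 17 genes, 16 adjusted over the list alone, median 3.11, 2.07e-31), and within experiment 1 the medians were -3.19 and 3.27. The neural list rose (7 of 15 up and 1 down, 9 and 2 adjusted over the list alone, median 1.59, 9.58e-08). STAT3 response genes fell (10 of 13, 11 adjusted over the list alone, 8.35e-13), as did Nodal and Smad response genes (8 of 12 down and 2 up, 8 and 3 adjusted over the list alone, 3.47e-06). Oxidative phosphorylation genes fell (11 of 40, 12 adjusted over the list alone, adjusted p = 0.000106, and adjusted p = 0.348 with an estimated correlation), with 5 genes without 96 h no-DOX exp2_2, 7 without 2iL exp2_1 and 0 within experiment 1. Cholesterol synthesis genes rose (11 of 20 up and 2 down, 13 and 2 adjusted over the list alone, adjusted p = 0.00494, and adjusted p = 0.364 with an estimated correlation), with 7 up without 2iL exp2_2 and adjusted p = 0.177 within experiment 1. In the order rose and fell over all genes, then adjusted over the list alone, the lists without a camera call began with general pluripotency (4 and 2 of 14, 4 and 2, adjusted p = 0.557).

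Further lists without a camera call after removal of 2iL follow in the same order. They were glycolysis (3 and 6 of 21, 3 and 6, adjusted p = 0.578), germline genes (5 and 3 of 10, 5 and 3, 0.634), endoderm (3 and 2 of 15, 4 and 2, 0.634) and p53 response (3 and 1 of 17, 5 and 2, 0.154). DNA methylation genes (4 and 3 of 10, 5 and 3, 0.141) and beta-catenin response genes (1 and 3 of 9, 1 and 5, 0.184) passed without 2iL exp1_2 (camera adjusted p = 0.0418 and 0.0307). DNA methylation genes passed without 2iL exp2_2 (0.0462), and beta-catenin response genes without 2iL exp1_1 (0.0466). ERK response genes gave 2 and 0 of 15 (2 and 0, 0.141) and passed within experiment 1 (0.0164). Stress genes gave 4 and 2 of 18 (4 and 2, 0.483), trophoblast genes 2 and 1 of 10 (2 and 1, 0.875) and fibroblast genes 2 and 1 of 5 (2 and 1, 0.791). Mesoderm genes gave 0 and 1 of 6 (0 and 1, 0.483). The 2-cell-like genes (2 measured, 0.483), mitochondrially encoded genes (11, 0.483) and proliferation genes (22, 0.739) held no called gene. Camera pointed up for endoderm genes with median -0.46 and mean -0.19, and up for fibroblast genes with median -0.01 and mean 0.82.

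The comparison of 96 h cells with and without DOX asked what differed when DOX was given to cells without 2iL. Part of the naive network was higher with DOX. Tbx3 rose from 13.0 ± 1.88 to 96.7 ± 14.9 CPM (log2 fold change 2.89 ± 0.25, n = 3 and 3; 2.94 within experiment 1 and 2.83 within experiment 2). Klf4 rose from 13.0 ± 2.42 to 78.7 ± 21.6 CPM (2.59 ± 0.27; 2.94 and 1.91). Zfp42 rose from 18.9 ± 3.70 to 81.9 ± 27.7 CPM (2.10 ± 0.29; 2.34 and 1.72), and Tfcp2l1 from 30.4 ± 7.22 to 97.6 ± 46.4 CPM (1.70 ± 0.31; 1.63 and 1.81). Nr0b1, an Esrrb target, rose by 4.62 ± 0.55 log2 units, the adhesion gene Jam2 by 4.49 ± 0.55 and the naive factor Klf5 by 2.56 ± 0.33. Nanog reached 32.8 ± 16.5 CPM without passing (adjusted p = 0.165), and Klf2 stayed at 43.6 ± 3.30 CPM (0.663). edgeR's quasi-likelihood test gave adjusted p = 9.55e-07 for Tbx3, 1.18e-05 for Klf4, 0.000156 for Zfp42 and 0.00333 for Tfcp2l1, which had 0.0843 within experiment 1. Pou5f1 (0.752) and Sox2 (0.0776) did not pass, but Sox2 passed without 96 h no-DOX exp1_2 (adjusted p = 0.0350).

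Genes of extraembryonic endoderm rose with DOX. Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635), which specifies primitive endoderm, reached 51.3 ± 8.57 CPM (log2 fold change 5.93 ± 0.67; 4.66 within experiment 2). Fitted values of 7.07 within experiment 1 and 6.96 without 96 h no-DOX exp2_2 are not exact. They rest on 0.294 and 0.431 CPM in the no-DOX libraries of experiment 1. Foxq1 (ENSMUSG00000038415, chromosome 13, 31556134 to 31560976), a forkhead factor, had 0 reads without DOX and reached 71.02 ± 18.4 CPM, a rise of at least 271-fold. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826), a basement membrane collagen, rose from 15.8 ± 3.76 to 186 ± 32.6 CPM (3.55 ± 0.29; 3.46 and 3.83). Pdgfra, a receptor of primitive endoderm, rose to 41.0 ± 35.4 CPM (log2 fold change 5.93 ± 0.88; 5.82 within experiment 1). This was 7.15 without 96 h no-DOX exp1_1 and 4.98 without 96 h DOX exp1_2. In experiment 2 Pdgfra held 0 CPM without DOX and 17.8 CPM with DOX, so no fold change is given. Nostrin, a trafficking gene, rose 237-fold by reads (95% counting interval 42.0 to 9421) and Pvalb, the calcium buffer parvalbumin, 152-fold (41.5 to 1259.8). edgeR's quasi-likelihood test gave adjusted p = 2.31e-05 for Gata6, 3.67e-07 for Foxq1, 3.89e-07 for Col4a1 and 0.000445 for Pdgfra. Sox17, a later endoderm factor, rose by 4.10 ± 1.10 log2 units (adjusted p = 0.0463), and this call was lost in 8 of 10 fits that left out a library (0.184 without 96 h no-DOX exp1_1). Its log2 fold change was 3.58 within experiment 1 (edgeR's quasi-likelihood test, adjusted p = 0.222). Without 96 h no-DOX exp1_2 the fitted value was 5.38, which rests on at most 0.294 CPM in the remaining no-DOX libraries. In experiment 2 Sox17 held 0 CPM without DOX and 8.30 CPM with DOX, so no fold change is given.

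Neural and epiblast genes changed in part with DOX. Sox3 (ENSMUSG00000045179, chromosome X, 60891366 to 60893430), a neural progenitor factor, fell from 288 ± 83.0 to 38.8 ± 19.6 CPM (log2 fold change -2.85 ± 0.35; -2.78 within experiment 1 and -2.93 within experiment 2). Nes, the neural filament gene nestin, fell from 53.5 ± 3.65 to 17.5 ± 1.16 CPM (-1.60 ± 0.33), a call lost within experiment 1 (-1.66; adjusted p = 0.0722). Dnmt3b fell from 1832 ± 205 to 929 ± 227 CPM (-0.98 ± 0.25), whereas Dnmt3a rose from 260.2 ± 38.3 to 741 ± 186 CPM (1.51 ± 0.26; 1.74 and 1.04). edgeR's quasi-likelihood test gave adjusted p = 4.77e-05 for Sox3, 0.00840 for Nes, 0.00155 for Dnmt3a and 0.0304 for Dnmt3b, a call lost in 5 of 10 fits (0.127 without 96 h no-DOX exp1_1) and within experiment 1 (0.386). Fgf5 (-1.69 ± 0.50; 0.0788), Otx2 (0.926) and Pou3f1 (0.368) did not pass. The DNA demethylase gene Tet2 rose by 3.25 ± 0.49 log2 units. Lefty2 rose from 8.93 ± 1.58 to 71.8 ± 21.0 CPM (3.02 ± 0.31; 2.83 and 3.30), Smad7 by 3.75 ± 0.41 log2 units and Tdgf1 by 2.50 ± 0.29. Lifr rose by 1.97 ± 0.36 log2 units, and the cyclin gene Ccnd1 fell from 255 ± 51.2 to 80.3 ± 3.84 CPM, with adjusted p = 0.000788 by edgeR and 0.0506 within experiment 1. Bmp4 rose by 2.99 ± 0.53 log2 units, and by 2.13 without 96 h DOX exp1_2 (3.42 within experiment 1 and 2.09 within experiment 2).

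In total, edgeR called 348 genes with DOX against no DOX (242 up and 106 down), 234 and 94 of them by at least 2-fold. Within experiment 1 alone 108 genes were called, 102 of them shared. The 2 DOX libraries of that fit were exp1_1 and exp1_2, the library that stood apart. A call lost within experiment 1 can therefore also come from that library or from the smaller groups. Leaving out single libraries gave 161 calls without 96 h no-DOX exp1_1, 181 without 96 h no-DOX exp2_2 and 260 without 96 h DOX exp1_2. The naive list rose (10 of 20 genes, 12 adjusted over the list alone, median log2 fold change 1.28, camera adjusted p = 1.22e-20), with 1.63 and 3.17e-16 within experiment 1. The endoderm list rose (13 of 15 genes, 15 adjusted over the list alone, median 4.10, 5.34e-41), with 3.92 within experiment 1 and 3.71 without 96 h DOX exp1_2. Endoderm genes called numbered 7 without 96 h no-DOX exp1_1, 8 without no-DOX exp1_2, 8 without no-DOX exp2_2 and 10 without any 1 DOX library. STAT3 response genes rose (4 of 13, 6 adjusted over the list alone, camera adjusted p = 8.55e-07, and 0.0376 with an estimated correlation). The STAT3 list includes Klf4, named above in the naive network, so in no comparison is it fully separate from that network. Nodal and Smad response genes rose (4 of 12, 6 adjusted over the list alone, 2.88e-08, and 0.00324 with an estimated correlation). The neural list was lower (1 of 15 down, with 5 down and 1 up adjusted over the list alone, median -0.74, 0.00148).

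Several list calls with DOX against no DOX did not hold with an estimated correlation. With fry, adjusted p was 0.0110 for the formative, 0.0103 for the general pluripotency, 0.0150 for the p53 and 0.0333 for the mitochondrially encoded list. For glycolysis and cholesterol synthesis fry did not pass (adjusted p = 0.103 and 0.156). The formative list was lower (1 gene up and 2 down of 17, with 2 and 6 adjusted over the list alone, median -0.58, camera adjusted p = 0.00335, and adjusted p = 0.0856 with an estimated correlation). General pluripotency was higher (2 up and 1 down of 14, with 4 and 1 adjusted over the list alone, adjusted p = 0.00335, and adjusted p = 0.107 with an estimated correlation). The p53 response was lower (1 of 17 down, 4 adjusted over the list alone, adjusted p = 0.00335, and adjusted p = 0.101 with an estimated correlation). Mitochondrially encoded genes were higher (2 of 11, 7 adjusted over the list alone, adjusted p = 1.87e-05, and adjusted p = 0.107 with an estimated correlation), with 0 called without 96 h no-DOX exp1_1 or without 96 h DOX exp1_2. Glycolysis (2 up and 2 down of 21, with 5 and 3 adjusted over the list alone) was higher at adjusted p = 0.0482, and adjusted p = 0.321 with an estimated correlation. That call was lost in 6 of 10 fits, with camera adjusted p = 0.327 without 96 h DOX exp2_1, and within experiment 1 (0.130). Cholesterol synthesis was lower with no called gene of 20, also adjusted over the list alone (adjusted p = 0.0313, and adjusted p = 0.376 with an estimated correlation). Without 96 h DOX exp1_2 camera gave 0.196.

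The remaining lists did not pass with all libraries with DOX against no DOX and are given as above. DNA methylation genes gave 3 and 1 of 10 (3 and 1, camera adjusted p = 0.0962), and passed without 2iL exp2_1 (0.0424) and within experiment 1 (0.0175). Trophoblast genes gave 1 and 0 of 10 (2 and 1, 0.104), mesoderm genes 1 and 0 of 6 (0.0962), germline genes 0 and 0 of 10 (1 and 0, 0.487), beta-catenin response genes 1 and 0 of 9 (0.487) and ERK response genes 1 and 1 of 15 (0.487). The 2-cell-like genes gave 1 and 0 of 2 (0.155) and passed in 4 of 10 fits: without 96 h DOX exp1_1 (camera adjusted p = 0.000207), no-DOX exp1_1 (0.00369), no-DOX exp1_2 (0.00278) and no-DOX exp2_2 (0.000470). Oxidative phosphorylation genes gave 1 and 0 of 40 (0.171) and passed without 96 h DOX exp1_2 (0.00162). Fibroblast genes (5, 0.388), stress genes (18, 0.487) and proliferation genes (22, 0.958) held no called gene. Camera pointed up for DNA methylation genes with median -0.05 and mean 0.44, and down for proliferation genes with median 0.01 and mean 0.03.

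Many genes that changed after removal of 2iL lay nearer to 2iL with DOX than without. Cells with and without DOX were sampled only at 96 h, so a smaller change cannot be told apart from a return. Klf4, Tbx3, Zfp42 and Lefty2 fell after removal and rose with DOX, and Sox3 and Nes went the other way. Of the genes lowered by removal, 142 were raised by DOX (58.7% of the 242 raised genes), against 21.5 for independent lists. Of those raised by removal, 78 were lowered by DOX (73.6% of 106), against 12.2. Changes in the same direction numbered 3 and 14, against 9.43 and 27.9. DOX-treated cells lay 26.6% of the way from no DOX to 2iL over the genes that changed (36.7% for lowered and 20.2% for raised genes). Of 2289 genes, 1760 (76.9%) lay closer to 2iL with DOX. In 20 simulated runs with the removal of 2iL kept and no effect of DOX, these values were 4.998% (3.96% to 6.17%) and 60.8% (59.5% to 62.7%). These runs took the observed group means as true and called 2900 to 3110 genes after removal of 2iL, against 2289 in the data. Their values therefore rest on a larger set of genes. Noise was also smaller in them relative to the differences, so these reference values may be too low. Single DOX libraries gave 24.8%, 32.3% and 29.8%, from log2 CPM with a prior count of 2 rather than fitted fold changes. The share was 39.1% and 38.7% with the 2iL libraries of experiments 1 and 2 used in turn for removal, and those of the other experiment for DOX. Differences between the 2iL libraries of the 2 experiments can raise this share without an effect of DOX. No simulation was run for this split. Both comparisons share the 3 libraries without DOX, which alone produces opposite changes: the correlation of fold changes was -0.43, against -0.52 (-0.54 to -0.51) in 20 simulated runs without any change. The covariance was -0.495, against -0.119 in these runs, a difference of -0.376. The runs without any change called at most 2 genes in either comparison, so their 0 opposite overlaps were nearly fixed. They do not show how many overlaps sharing gives when many genes change. The 3 libraries cannot be split into separate pairs, so part of the excess may come from sharing. The overlap of 142 was 75 without 96 h no-DOX exp1_1 and 89 without no-DOX exp2_2, and that of 78 was 34 without either of these libraries and 39 without 96 h DOX exp2_1.

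Comparison of DOX-treated cells with 2iL showed which differences from the naive state were left. Klf4 stayed lower than in 2iL (log2 fold change -1.59 ± 0.24, n = 4 and 3), as did Tfcp2l1 (-3.21 ± 0.31), Nanog (-2.73 ± 0.30), Klf2 (-2.57 ± 0.24) and Esrrb (-4.10 ± 0.34). Dnmt3a (4.62 ± 0.26), Dnmt3b (2.40 ± 0.23), Otx2 (3.03 ± 0.32) and Pou3f1 (4.31 ± 0.35) stayed higher. Klf5 (376 ± 206 CPM) and Nr0b1 (34.3 ± 18.7 CPM) did not pass against 2iL. Gata6 was higher than in 2iL by 6.25 ± 0.62 log2 units, Col4a1 by 5.72 ± 0.30 and Foxq1 by 6.14 ± 0.46. Without 2iL exp1_2 the fitted value for Gata6 was 7.60, which rests on at most 0.614 CPM in the remaining 2iL libraries. Nostrin had 0 reads in 2iL and was at least 93.0-fold higher. Timp3, a protease inhibitor gene of fibroblasts, was higher by 7.43 log2 units but by 3.36 without 96 h DOX exp1_2, and its call was lost in 7 of 10 fits and within experiment 1 (adjusted p = 0.210). edgeR's quasi-likelihood test gave adjusted p = 4.64e-10 for Dnmt3a, 2.10e-10 for Col4a1, 6.88e-07 for Gata6 and 7.86e-05 for Klf4. It called 1870 genes (1104 up and 766 down; 1005 and 574 by at least 2-fold), 926 within experiment 1 with 849 shared, and 1569 without 96 h DOX exp1_2.

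The naive list stayed below 2iL (17 of 20 genes, 17 adjusted over the list alone, median log2 fold change -1.62, camera adjusted p = 3.59e-19). The formative list stayed above (14 of 17, 17 adjusted over the list alone, 2.82, 3.29e-27), as did endoderm genes (14 of 15, 15 adjusted over the list alone, 5.20, or 4.88 with genes at 0 placed at their bound, 4.14e-25). Endoderm genes called numbered 11 without 96 h DOX exp1_2. Neural genes were higher (6 of 15, 6 adjusted over the list alone, 0.000395), as were DNA methylation genes (5 up and 3 down of 10, with 6 and 3 adjusted over the list alone, 0.00216). DNA methylation genes numbered 3 up without 2iL exp2_1 and 1 down without 2iL exp1_2. STAT3 response genes were lower (7 of 13, 7 adjusted over the list alone, adjusted p = 2.83e-06, and adjusted p = 0.0575 with an estimated correlation), with 4 genes without 2iL exp2_1. General pluripotency was higher (5 of 14, 5 adjusted over the list alone, adjusted p = 0.00309, and adjusted p = 0.0887 with an estimated correlation, 0.115 within experiment 1). ERK response genes were higher (3 up and 1 down of 15, with 4 and 1 adjusted over the list alone, adjusted p = 0.0155, and adjusted p = 0.110 with an estimated correlation). Oxidative phosphorylation genes were lower (6 of 40, 6 adjusted over the list alone, adjusted p = 0.00155, and adjusted p = 0.348 with an estimated correlation), with 3 genes without 2iL exp1_1 or without 2iL exp2_2, 1 without 2iL exp2_1 or without 96 h DOX exp1_2, and 0 within experiment 1.

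Other lists did not pass with all libraries between DOX-treated cells and 2iL. Mitochondrially encoded genes (3 and 0 of 11, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0504) passed in 6 of 10 fits, with 0.00580 without 96 h DOX exp1_1, 0.0146 without 96 h DOX exp2_1, 0.0452 without 2iL exp2_1, and 0.0433, 0.0492 and 0.0468 without no-DOX exp1_1, exp1_2 and exp2_2. They passed within experiment 1 (0.0187), but without 96 h DOX exp1_2 held 0 called genes (0.319). The lists also held Nodal and Smad response genes (1 and 2 of 12, 1 and 2, 0.150) and trophoblast genes (4 and 1 of 10, 5 and 2, 0.258). Cholesterol synthesis genes (4 and 1 of 20, 6 and 1, 0.161) passed without 96 h DOX exp1_2 (7 up, camera adjusted p = 0.00847). Only 1 was up without 2iL exp2_2. Beta-catenin response genes (1 and 3 of 9, 1 and 3, 0.341) passed without 96 h DOX exp2_1 (camera adjusted p = 0.0376) and without 96 h no-DOX exp1_1 (0.0470). Germline genes gave 5 and 3 of 10 (5 and 3, 0.341), fibroblast genes 2 and 1 of 5 (3 and 1, 0.361), glycolysis genes 7 and 5 of 21 (7 and 6, 0.554) and stress genes 2 and 2 of 18 (0.730). Proliferation genes gave 1 and 2 of 22 (3 and 3, 0.730), p53 response genes 1 and 0 of 17 (0.780), mesoderm genes 1 and 0 of 6 (0.820) and 2-cell-like genes 1 and 0 of 2 (1 and 1, 0.820), which passed without 96 h DOX exp1_1 (0.0308). Camera pointed up for mesoderm genes with median -0.12 and mean -0.34, down for p53 response genes with median -0.14 and mean 0.01, and down for proliferation genes with median 0.06 and mean 0.01.

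**Figure D1:**
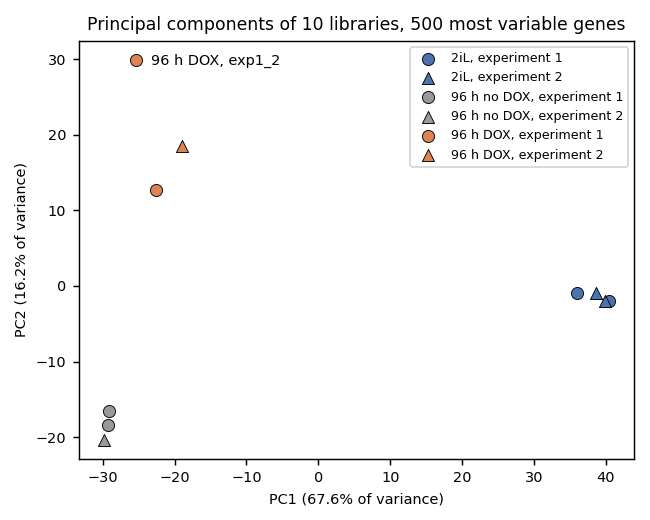
Principal components of the 10 libraries, coloured by group.

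**Figure D2:**
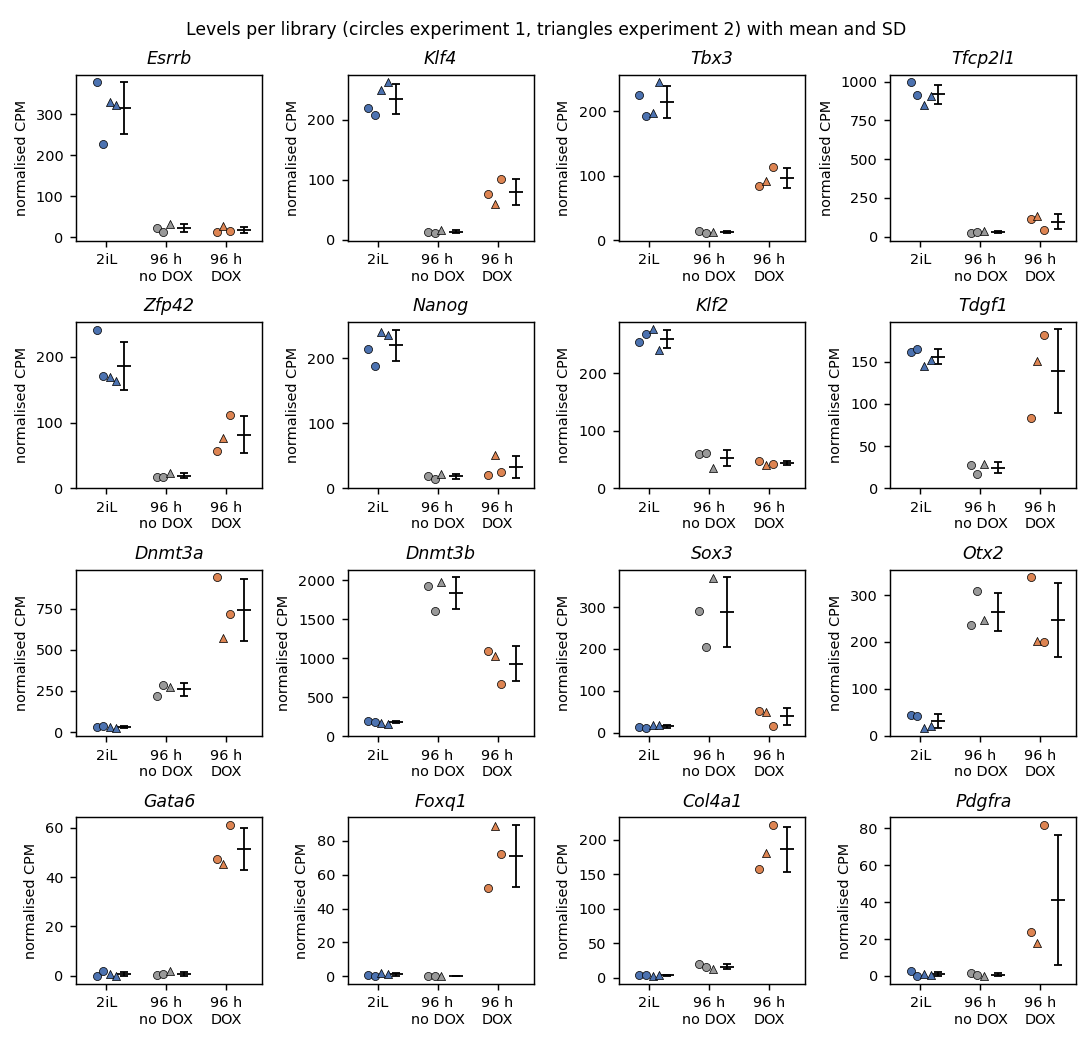
CPM of named genes in each library of the 3 groups.

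**Figure D3:**
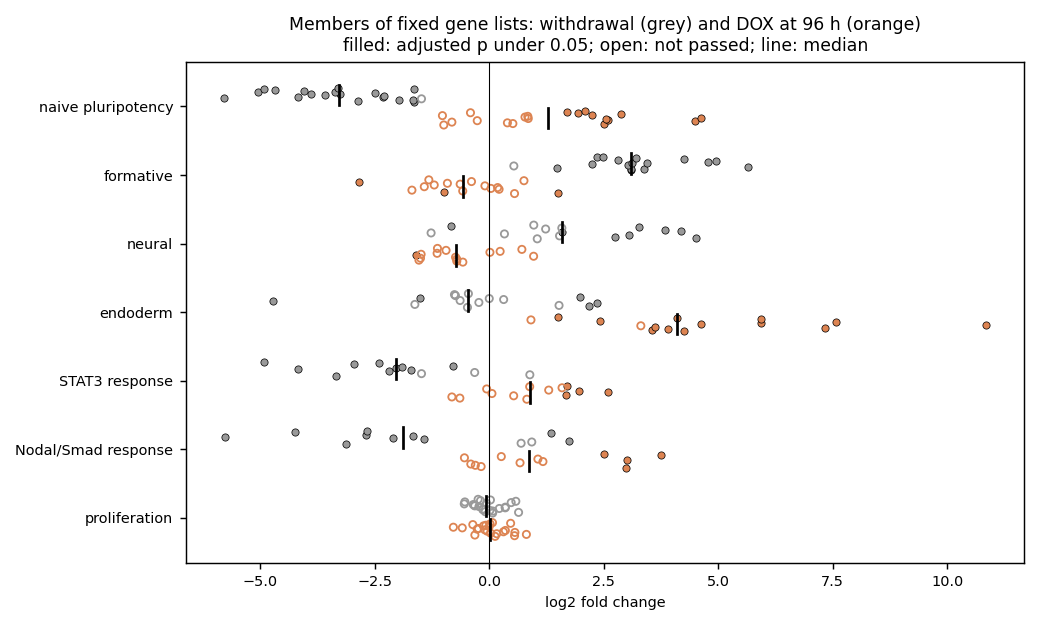
Log2 fold changes of the genes of selected lists after removal of 2iL and with DOX against no DOX. Foxq1 is drawn at its fitted values, which are not bounds.

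**Figure D4:**
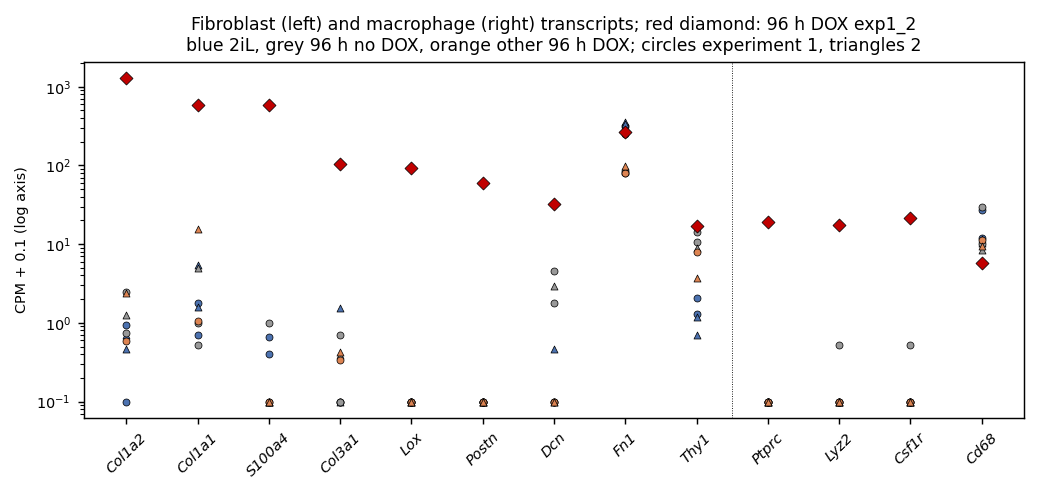
CPM, without TMM scaling, of marker genes of other cell types in each library, drawn with an offset of 0.1 CPM.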

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

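The tests on Esrrb, on the collagen share and on the endoderm list were chosen after the results they weigh had been seen, whereas the splits of the libraries, the second fibroblast list and the Xist ratio were set before. Splits that mixed the 3 DOX and 3 no-DOX libraries called 0 genes at most, against 348 for the real split, which ranked 1 of 10. With 10 splits a share below 0.05 cannot be reached. Where groups differ, a mixed split shrinks the difference and adds it to the spread within groups. Low values in mixed splits were therefore likely in advance, also for the other comparisons and the list medians below. The real splits of removal of 2iL (2289 genes, highest other 309) and of DOX against 2iL (1870, highest other 194) ranked 1 of 35. For list medians with DOX against no DOX the real split ranked 1 of 10 for naive (1.28, highest other 0.74), formative (size 0.58, highest other 0.36) and neural genes (size 0.74, highest other 0.39).

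Esrrb was not higher with DOX (log2 fold change -0.32 ± 0.33), although DOX was given to induce its construct. Too few reads to see a 2-fold rise was argued against by the upper 95% bound of 0.38. A single wrong label among the 96 h libraries was argued against by the naive list, where the lowest DOX library lay 1.02 log2 units above the highest no-DOX library. Transcripts of the construct that lack the counted 3′ end may explain the level, and the same value of -0.32 leaves this open, because the construct sequence is not given in the sources used here.

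Fibroblast genes were high in 96 h DOX exp1_2 alone: 14 markers summed to 3109.4 CPM there, 8.46 times the highest other library, and 11 of 14 were highest there. RNA of fibroblasts or feeder cells in this library may be the source; a second fibroblast list gave a ratio of 3.31, between the bounds of 2 and 5 set in advance, which leaves it open (17 of 20 genes were highest there, and Pcolce alone held up to 114 CPM in 2iL). A list of 12 further fibroblast genes gave a ratio of 47.5 (1709 CPM against at most 36.0), but its genes were picked because they were high in this library, so it is no test. An effect of DOX shared by all DOX libraries was argued against, since the other DOX libraries held at most 0.935% of its collagen level. Cells that turned into mesenchyme in this culture were predicted to leave both Xist and the macrophage list within 3 times the highest other library. The ratios were 1.07 and 3.13, so the macrophage part was not met. Of 12 macrophage genes 7 were highest there. Ptprc, Aif1 and Csf1r held 19.1, 21.5 and 21.5 CPM, against at most 0.424 CPM elsewhere, while Adgre1, C1qa and C1qb held 0 CPM there. These values argue against this source for the macrophage genes. For the fibroblast genes it stays open, because foreign cells can be male and Xist then cannot decide.

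Endoderm genes such as Gata6, Foxq1 and Col4a1 rose with DOX (list median 4.10). Fibroblast RNA in 96 h DOX exp1_2 was argued against, since the median was 3.71 without that library. Fewer pluripotent cells, with markers of every other cell type raised, was argued against by the neural list, whose median was -0.74. The mesoderm (0.32), trophoblast (0.71) and fibroblast medians (0.69) were positive, without a camera call. Without 96 h DOX exp1_2 they were 0.31, 0.36 and 0.0016, so the fibroblast median rested on that library. A loss of pluripotent cells to endoderm alone need not raise neural genes, so the neural list cannot decide it. DOX itself, without Esrrb, could give the same median of 4.10 and stays open.

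Of 150 values tested in the 2iL group, 16 lay past the limit of Dixon's test. Tdrd1, Arap3, Gcm1, Susd3, Pvalb, Atp1a4 and Ybx2 had reads in a single 2iL library, which fixes the ratio at 1. Without the 8 values at 0 in 3 or 4 libraries, 9 of 142 (6.34%) remained, near the 1 in 20 of chance. They included the formative list (0.918) and the mitochondrially encoded list (0.863), both low in 2iL exp1_1, Zfp42 (0.910), Sox17 (0.868), Col4a1 (0.862), Tuba3a (0.961), Pfkp (0.955) and Ebp (0.863).

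The effect of removal of 2iL differed between experiments for 1 gene, Egr1, named after its values had been seen (experiment 1 minus experiment 2, 5.83 ± 0.80 log2 units; edgeR's quasi-likelihood test, adjusted p = 0.0152; 854 genes at unadjusted p < 0.05; 4 residual degrees of freedom). Egr1 held 1.33 and 3.22 CPM in 2iL of experiment 1, and 35.01 and 19.96 CPM in experiment 2. The effect of DOX differed between experiments for 0 genes by edgeR (614 at unadjusted p < 0.05; smallest adjusted p = 0.857). Macrophage genes summed to 98.1 CPM in 96 h DOX exp1_2 (8.33 to 31.4 elsewhere; Csf1r 21.5 CPM, Ptprc 19.1 CPM), and the liver gene Alb reached 23.9 CPM there.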

How the results depend on the processing

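The 348 genes called with DOX against no DOX became 564 without a filter, 212 with only the 2 groups compared, 108 in experiment 1 and 161 to 358 without single libraries. The cause was not tested. Removal of 2iL called 2289 genes, 1226 in experiment 1 and 1779 to 2718 without single libraries; DOX against 2iL called 1870, 926 and 1408 to 1916. With the experiment as replicate block the counts were 2244, 347 and 1815. With experiment and number as replicate block, DOX against no DOX gave 159, and the overlaps of 142 and 78 became 80 and 28. The numbers did not pair libraries: residuals of libraries with the same experiment and number correlated at 0.0268 on average (-0.0953 to 0.205). DESeq2 called 2609, 519 and 2239 genes.

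Genes lowered by removal of 2iL and raised by DOX (142) numbered 54 in experiment 1, 69 with only 2 groups, 93 with limma-voom and 75 to 137 without single libraries. Those raised by removal and lowered by DOX (78) numbered 129 without a filter, 13 in experiment 1 and 34 to 75 without single libraries. The share of change absent with DOX (26.6%) ran from 25.2% to 32.4% without single libraries. It was 39.1% and 38.7% with removal and DOX measured against 2iL libraries of different experiments, which can itself raise the share. The formative list with DOX gave camera adjusted p from 0.000459 to 0.0856. The naive list kept its call in 22 fits (highest 0.000216) and the neural list in 22 (highest 0.0376).

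Of the named genes, 64 of 72 kept their call after removal of 2iL in every fit without a library, 29 of 44 with DOX against no DOX, and 61 of 74 with DOX against 2iL. Among other results, 4889 of 5259 gene values and 1323 of 1387 list values stayed the same. No gene called in either fit changed sign, but 31 values of genes without a call did, such as T within experiment 1 (0.38). List medians changed sign in 74 fits, such as mesoderm (1.07), beta-catenin (0.30) and germline genes (-0.37) after removal of 2iL within experiment 1. Of these, 2 fits held a call, both for DNA methylation genes with DOX (0.42 within experiment 1, 0.08 without 2iL exp2_1). Alternatives added after the data were seen gave 2290, 352 and 1874 genes without Gm42418, and 2745, 297 and 1644 with the experiment as replicate block and 96 h DOX exp1_2 left out. Endoderm genes not expressed by fibroblasts rose with DOX (8 genes, median 4.62, camera adjusted p = 4.95e-25). On simulated data, among genes that passed the filter, the DOX test recovered 2.08% at a 1.5-fold change, 16.3% at 2-fold, 69.6% at 4-fold and 88.3% at 8-fold. There, 14 of 272 calls (5.15%) were false.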

Other observations

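The lists below were chosen after the values had been seen, so their p-values are no test of a prior expectation. Basement membrane genes were higher with DOX against no DOX. Their list shares members with the endoderm list, such as Col4a1 and Sparc, so this is no separate result. Col4a1 (3.55 ± 0.29 log2 units), Col4a2 (3.90 ± 0.49), Lama1 (2.42 ± 0.45), Nid1 (3.45 ± 0.67) and Nid2 (1.48 ± 0.27) rose and kept their call without any 1 library, but that of Nid2 was lost within experiment 1 (1.27; edgeR's quasi-likelihood test, adjusted p = 0.170). Without 96 h DOX exp1_2, which held the most Nid1, its log2 fold change was 2.40, and that of Lama1 was 1.92. Calls for Sparc (up) and Agrn (down) were lost without that library (0.75 and -0.84 log2 units; edgeR's quasi-likelihood test, adjusted p = 0.219 and 0.103) and in other fits. The list median was 1.48 over 11 genes (camera adjusted p = 8.54e-13, and 0.00694 with an estimated correlation), and 1.51 without 96 h DOX exp1_2. Within experiment 1 it was 1.501 (5.02e-12, and 0.115 with an estimated correlation).

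Epithelial junction genes were lower with DOX as a list. Cdh1, the gene of E-cadherin, went from 4298 ± 1610.0 to 1577 ± 736 CPM (log2 fold change -1.44 ± 0.37), Cldn7 from 67.2 ± 8.86 to 23.5 ± 10.7 CPM, and the splicing factor gene Esrp1 from 67.01 ± 18.0 to 23.1 ± 6.88 CPM. All 3 calls were lost without 96 h no-DOX exp1_1 (edgeR's quasi-likelihood test, adjusted p = 0.0954, 0.129 and 0.0541) and without no-DOX exp2_2 (0.205, 0.0694 and 0.0814). The desmosome gene Dsp rose by 2.19 ± 0.43 log2 units. Of 16 genes 8 fell and 1 rose (median -1.22; camera adjusted p = 5.22e-06, and 0.0247 with an estimated correlation), but 3 fell without 96 h no-DOX exp2_2 or DOX exp2_1, 4 without no-DOX exp1_1 or exp1_2, and 0 within experiment 1. The median was -0.95 without 96 h DOX exp1_2. With an estimated correlation adjusted p was 0.0668 without no-DOX exp1_2, 0.0615 without DOX exp2_1 and 0.124 within experiment 1. After removal of 2iL 10 of these genes rose (median 1.62; 5.80e-08, and 0.0172 with an estimated correlation, or 0.117 within experiment 1).

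Some genes linked to Notch fell with DOX. Dtx1 fell from 89.9 ± 11.2 to 18.9 ± 9.05 CPM (log2 fold change -2.19 ± 0.35), Dtx4 from 90.3 ± 14.8 to 24.6 ± 12.1 CPM, and Hes6 from 245 ± 39.2 to 73.7 ± 32.0 CPM, each kept without any 1 library. Within experiment 1 Dtx4 did not pass (-1.72; edgeR's quasi-likelihood test, adjusted p = 0.0529). The direct Notch targets Hes1 (0.10; edgeR's quasi-likelihood test, adjusted p = 0.922), Hey1 (0.09; 0.978), Hes5 (-0.71; 0.663) and Nrarp (-0.47; 0.764) did not pass, nor did the ligand and receptor genes Dll3 (-1.91; 0.157), Jag1 (-1.23; 0.214), Notch1 (-0.81; 0.410) and Notch3 (-0.70; 0.394). The list of 12 genes, which mixes targets with ligands and receptors, was lower (median -0.94; camera adjusted p = 1.75e-06, and 0.00677 with an estimated correlation), and its median was -1.45 without 96 h DOX exp1_2. Within experiment 1 camera gave 4.20e-07, and 0.0904 with an estimated correlation. After removal of 2iL 6 of 12 rose and 1 fell (median 1.30; 0.00250, and 0.0342 with an estimated correlation). With an estimated correlation this was 0.0590 without 2iL exp1_2, 0.0523 without 2iL exp2_2 and 0.117 within experiment 1.

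T and Sp5, both targets of beta-catenin, had higher levels in 2iL of experiment 2, a difference that was not tested. T, a gene of the primitive streak, held 4.33 and 1.46 CPM in experiment 1 and 70.6 and 62.5 CPM in experiment 2. Sp5 held 31.6 and 40.1 CPM in experiment 1 and 181 and 197 CPM in experiment 2. T did not pass after removal of 2iL (log2 fold change -3.70 ± 1.44; edgeR's quasi-likelihood test, adjusted p = 0.116), but passed without 2iL exp1_1 (adjusted p = 0.0478) and without 2iL exp1_2 (0.00974). Its change was 0.38 within experiment 1 (edgeR's quasi-likelihood test, adjusted p = 0.893). In experiment 2, T held 0.294 CPM in the 1 library at 96 h without DOX. The fitted change of -7.65 there is therefore not exact.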
